A study of Mus musculus with 42 samples.

How the data were processed

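Total RNA from snap-frozen, microdissected striatum and hippocampus of C57BL6 mice was hybridised as biotin-labelled cRNA to Affymetrix arrays. The mice were wild type (WT) or labelled as knockout (KO) for PDE10A, and had received vehicle or an inhibitor of PDE10 (PDE10i). The compound, its dose and the time between dosing and dissection are not given in the sources used here. The 42 arrays fall into 8 groups by their titles. In striatum there were 5 WT vehicle, 6 WT inhibitor, 5 KO vehicle and 4 KO inhibitor arrays. In hippocampus there were 6 WT vehicle, 6 WT inhibitor, 5 KO vehicle and 5 KO inhibitor arrays. Nothing in the labels says that the arrays of a group came from separate animals, so p-values measure only the spread between these samples, which may be technical. The number of arrays limits the precision.

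The authors deposited 1 table of log2 expression values for 45101 probe sets, made with RMA per the submitters' processing notes. RMA subtracts a background, normalizes quantiles across arrays and summarises the probes of a set on the log2 scale, so differences in total RNA between arrays are removed. Whether all arrays were processed in a single run is not given in the sources used here. The scale was read from the values, which ran from 2.55 to 15.1, and no centring of genes was seen. The array medians lay between 6.05 and 6.12, and the median over a group's arrays averaged between 6.08 and 6.11. Direction is not at issue, because each array carried a single labelled sample. No arrays held identical values: the most alike pair (r = 0.997 over all probe sets) still differed with an SD of 0.167.

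Probe sets were named from the platform annotation given for this table. After removal of 64 control probe sets, 34945 had a single gene and were used, 932 listed several genes and were not named, and 9160 had no listed gene. Gene identifiers were matched to the RefSeq gene table of assembly GRCm38.p6 for 34741 of the 34945 probe sets, and the annotation's own symbol was kept for 204. That table served only for names, chromosomes and gene order. Of the 436 entries in the gene lists, 398 matched a tested gene, and the rest were not analysed here. For each of 18193 genes the probe set with the highest mean over the 42 arrays was used, and 9010 genes had more than 1 probe set.

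Differences between groups were fitted on the deposited log2 values with limma 3.58.1 in R 4.3.3 (lmFit and eBayes, two-sided, Benjamini-Hochberg adjustment over 18193 genes, threshold 0.05). The 4 groups of a region shared a fit. Contrasts between regions used all 42 arrays in 8 groups. A fold is 2 raised to the log2 difference, and errors on log2 differences are standard errors (SE). Lists of genes for neuron classes, signalling and stress pathways and other cell types, 30 in all, were tested with camera at a preset correlation of 0.01, again with an estimated correlation, and with fry, and adjusted over the 30 lists of a comparison. Genes of a list were also adjusted over the list alone. Groups, tests, lists, alternatives and the rule for naming genes were set before the data were examined. The rule names Pde10a, the 8 largest rises and 8 largest falls past the threshold, and up to 3 members of each list with the smallest p among those past it. Where no member of a list passed, the member with the smallest p may be given with its values. Clone and predicted names were left out and counted.

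The striatal knockout and inhibitor effects share the WT vehicle arrays. Their correlation and covariance were therefore set beside 100 simulated pairs of unchanged groups that share such arrays, and beside the 20 ways of giving 2 of the 5 vehicle arrays to either effect and the remaining 3 to the other. Simulated values had the residual spread of each gene and no correlation between genes. After the values had been seen, the genes with the smallest p in either effect, as many as had passed, were also chosen within each such split and followed in the other effect, with and without the doubted arrays.

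A score from genes of chromosome 17, the chromosome of Pde10a, was computed for each array after the values had been seen. It uses 15 genes per region from anywhere on that chromosome, those with the smallest p for the genotype label in the other region, and is scaled so that the median of the WT vehicle arrays is 0 and that of the KO inhibitor arrays is 1. Arrays on the other genotype's side of 0.5 were left out in an added alternative. Because the score rests on genes chosen for the genotype label, this favours chromosome 17 genes in fits of the knockout effect. Other added alternatives left out the striatal array with the highest Gapdh difference of each group, or took that difference or the mean of glutamatergic markers as a covariate. The Gapdh difference is the log2 signal of a 3' control probe set minus that of a 5' probe set, and rises as RNA is shortened.

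The fits were tested on simulated data with the real residual spread, in 4 runs of 200 changed genes among 18193. For the striatal inhibitor effect in WT, 40% of genes planted at 1.25-fold were recovered, 83% at 1.5-fold and 98% at 2-fold. For the striatal knockout effect the shares were 34.5%, 82.5% and 97%, and for the striatal inhibitor effect in KO 28.5%, 80% and 96.5%. For the hippocampal inhibitor effect in WT they were 62%, 96% and 99.5%, and for the hippocampal knockout effect 56%, 95% and 98.5%. For the striatal genotype by treatment difference they were 10.5%, 48.5% and 92%. With no planted change these 6 comparisons made 0 calls, while the inhibitor effect in KO hippocampus made 2 and the region by knockout difference 1 over the 4 runs. A list shifted by 0.2 in a simulation of the striatal inhibitor effect was called in 10 of 10 runs by each of the 3 list tests, and a planted covariance of 0.0110 was recovered as 0.0110. Genes were drawn independently in these simulations, while the estimated correlation of that list in the real striatal arrays was 0.20. The runs thus do not show how often the list tests would call such a shift in the real data.

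Alternatives covered the probe sets per gene, a filter on dim genes, quantile normalization and median centring, the variance model, array weights, the arrays in the fit, a block on the number in the title, genes of chromosome 17, and leaving out each array in turn.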

Results

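The data describe gene expression in striatum and hippocampus of WT mice and of mice labelled as PDE10A knockouts, each after vehicle or a PDE10 inhibitor. PDE10A is a phosphodiesterase that breaks down the second messengers cAMP and cGMP and is abundant in striatal projection neurons. Each group held 4 to 6 arrays. The design asks how the drug changes transcription in WT tissue, whether absence of the enzyme gives a similar profile, and whether the drug acts where its target is absent.

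Pde10a itself, the targeted gene, was measured by 5 probe sets. In striatum its mean log2 signal was 12.32 ± 0.26 (SD, n = 5) in WT vehicle, 12.49 ± 0.25 (n = 6) in WT inhibitor, 12.35 ± 0.22 (n = 5) in labelled KO vehicle and 12.42 ± 0.40 (n = 4) in labelled KO inhibitor arrays. Single arrays lay between 12.02 and 12.99. In hippocampus the means were 9.0 ± 0.04 (n = 6), 9.27 ± 0.52 (n = 6), 9.47 ± 0.45 (n = 5) and 9.69 ± 0.14 (n = 5) in the same order of groups, with single arrays between 8.54 and 10.16. The labelled KO arrays were thus not lower: the knockout difference was 0.03 ± 0.16 (SE, adjusted p = 0.997) in striatum and 0.47 ± 0.20 (adjusted p = 0.71) in hippocampus. None of the other 4 probe sets differed with genotype past the threshold either. In striatum, 1 of them was lower by 0.33 on average in KO (-0.33 ± 0.20, adjusted p = 0.992 over all probe sets). The part of the gene removed in these mice is not given in the sources used here, and a probe set outside the removed part cannot show its loss. Pde10a thus gives no check on absence of the gene. In hippocampus its signal still set single arrays apart, picked out after the values were seen. KO vehicle 25 and 26 (9.04 and 9.08) lay near the WT vehicle arrays (8.94 to 9.04), the other KO arrays at 9.51 to 10.16. WT inhibitor 12 and 14 (9.88 and 9.84) lay among the latter, the other WT inhibitor arrays at 8.54 to 9.29. In striatum the groups overlapped. All statements on KO arrays below rest on the labels.

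Other genes of chromosome 17 give another view of the labels. Of 96 genes with an unadjusted p under 0.001 for the striatal knockout effect, 16 lay on chromosome 17, the chromosome of Pde10a, which holds 834 of the 18193 tested genes (Fisher's exact test, two-sided, p = 7.0e-06). A score from 15 genes of the whole chromosome, chosen in the other region for their difference with the genotype label, was near 0 in all 11 WT vehicle arrays (-0.13 to 0.06) and near 1 in all 9 KO inhibitor arrays (0.91 to 1.11). The other groups were mixed. In striatum, KO vehicle 25 scored 0.19, while WT inhibitor 13, 14 and 15 scored 0.63, 0.78 and 0.61. In hippocampus, KO vehicle 25 and 26 scored -0.02 and 0.09, and WT inhibitor 12 and 14 scored 1.05 and 0.83. These 8 arrays carry a score on the other genotype's side of 0.5. Those in hippocampus are the arrays named above for their Pde10a signal, a gene left out of the score. Counts without them are an alternative chosen after the values were seen.

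**Figure D1:**
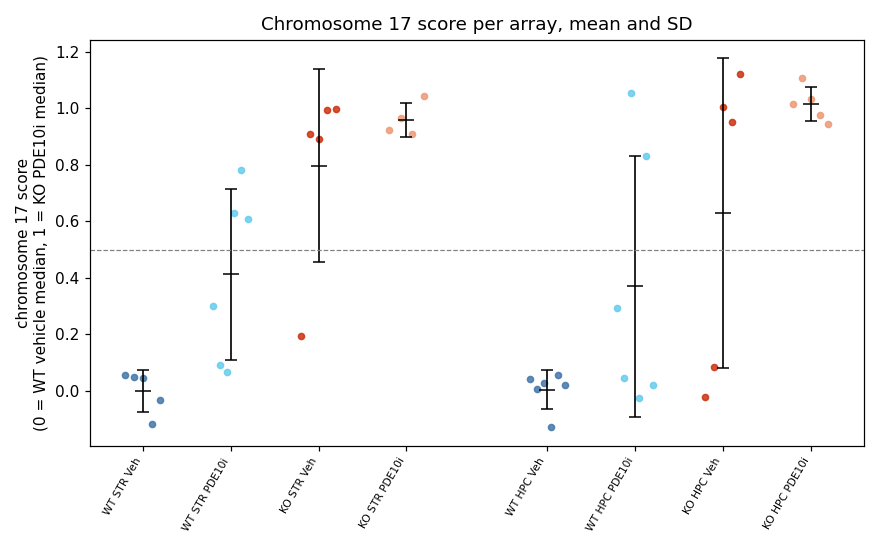
Score of 15 chromosome 17 genes per region (vertical axis, no unit; 0 is the median of WT vehicle arrays and 1 that of KO inhibitor arrays) for each array of the 8 groups, with a line at 0.5. In striatum KO vehicle 25 (0.19) and WT inhibitor 13, 14 and 15 (0.61 to 0.78) lie on the side of the other genotype.

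In WT striatum the inhibitor raised a small set of genes. Nnat, which codes for neuronatin, a membrane protein involved in calcium handling, rose 2.69-fold (log2 1.43 ± 0.17 SE, n = 6 against 5, adjusted p = 0.00103). Irak3, a brake on Toll-like receptor signalling, rose 2.34-fold (1.22 ± 0.25), Pde1c, a calmodulin-dependent phosphodiesterase for cAMP and cGMP, 1.94-fold (0.95 ± 0.16), and Fam43a 1.84-fold (0.88 ± 0.12). Coch (1.67-fold), the endothelial transcription factor Sox17 (1.66-fold), Ppp1r2, an inhibitor of protein phosphatase 1 (1.59-fold), and the heparan sulfate sulfotransferase gene Hs6st2 (1.56-fold) complete the 8 largest rises. Clspn, an adaptor of the DNA replication checkpoint, fell most, 2.78-fold (log2 -1.47 ± 0.20, adjusted p = 0.00316; its other probe set 0.02 ± 0.09), ahead of the protease inhibitor gene Serpinb1b (2.29-fold; -1.19 ± 0.24). The further falls were Rasgef1c (1.63-fold), Gask1b (1.60-fold), Ptprv (1.58-fold), the collagen gene Col6a2 (1.55-fold), the calcium/calmodulin kinase kinase Camkk2 (1.53-fold) and the activin-binding protein gene Fst (1.48-fold).

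Among the fixed lists, 1 of 18 phosphodiesterases other than Pde10a rose (Pde1c) and none fell. Of 19 genes of transmitter synthesis and transport, Abat, which breaks down GABA, rose 1.29-fold (0.37 ± 0.07, adjusted p = 0.0356). Adjusted over the list alone, 6 rose, among them the GABA-synthesising Gad1 (0.28 ± 0.06) and Gad2 (0.53 ± 0.13) and the vesicular GABA transporter Slc32a1 (0.41 ± 0.11). The list's median change was 0.08, its mean -0.01, and its camera test pointed up (adjusted p = 0.0482; adjusted p = 0.492 with an estimated correlation). No member of the other lists passed over all genes. Pdyn, the dynorphin precursor of direct pathway neurons, had a log2 change of 0.82 ± 0.18 (adjusted p = 0.0791), and Nts, which codes for neurotensin and was chosen after its values were seen, 2.48 ± 0.65 (adjusted p = 0.151). Adjusted over the list alone, these 2 of 19 neuropeptide genes passed.

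Several lists shifted as sets in camera with a preset correlation. Of 78 nuclear genes of oxidative phosphorylation 71 had a positive change (median 0.10, adjusted p = 2.18e-10; adjusted p = 0.492 with an estimated correlation). All 10 vascular markers were positive (median 0.28, adjusted p = 5.94e-06), with Rgs5 at 0.69 ± 0.17, Cldn5 at 0.40 ± 0.15 and Esam at 0.34 ± 0.12 passing when adjusted over the list alone. Shared striatal projection neuron genes were positive for 21 of 25 (adjusted p = 2.70e-04, 1 adjusted over the list alone) and direct pathway markers for 9 of 10 (adjusted p = 0.0482, 1 higher and 1 lower adjusted over the list alone). All 9 markers of cortical and hippocampal glutamatergic neurons were negative (median -1.07, adjusted p = 2.55e-06, 2 adjusted over the list alone), as were 7 of 10 astrocyte markers (adjusted p = 0.0482, 1 adjusted over the list alone). With an estimated correlation the adjusted p was 0.492 for the vascular, glutamatergic and astrocyte lists, 0.851 for the shared striatal list and 0.624 for the direct pathway list, and fry called none of the 30 lists by direction, while its test for change in either direction passed for the transmitter genes (adjusted p = 1.95e-04). The glutamatergic markers averaged log2 7.48 ± 0.93 (SD, n = 5) on WT vehicle and 6.46 ± 0.60 (n = 6) on WT inhibitor arrays, with single arrays between 6.07 and 8.34 and between 5.94 and 7.60. Early response genes were positive for 10 of 30 (adjusted p = 0.753).

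In all, 33 of 18193 genes passed (18 higher and 15 lower), against 1741 with an unadjusted p under 0.05. A feature common to the WT vehicle arrays of striatum, apart from the drug, would appear in this and every other comparison with them. Without WT inhibitor 13, 14 and 15 and KO vehicle 25 the count was 769 (567 higher), and 86 without the 4 arrays of high Gapdh difference. It was 195 with array weights, 20 with only the groups compared, 19 with the gene mean of probe sets, 18 with any probe set and 10 with the glutamatergic marker mean as a covariate. Single arrays moved it too: leaving out WT inhibitor 15 gave 4 genes, WT vehicle 5 gave 5, WT inhibitor 11 gave 6, WT vehicle 3 gave 9, WT inhibitor 12 gave 11, WT inhibitor 10 gave 14, WT vehicle 4 gave 15, WT vehicle 2 gave 17, WT vehicle 1 gave 18 and WT inhibitor 14 gave 73.

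**Figure D2:**
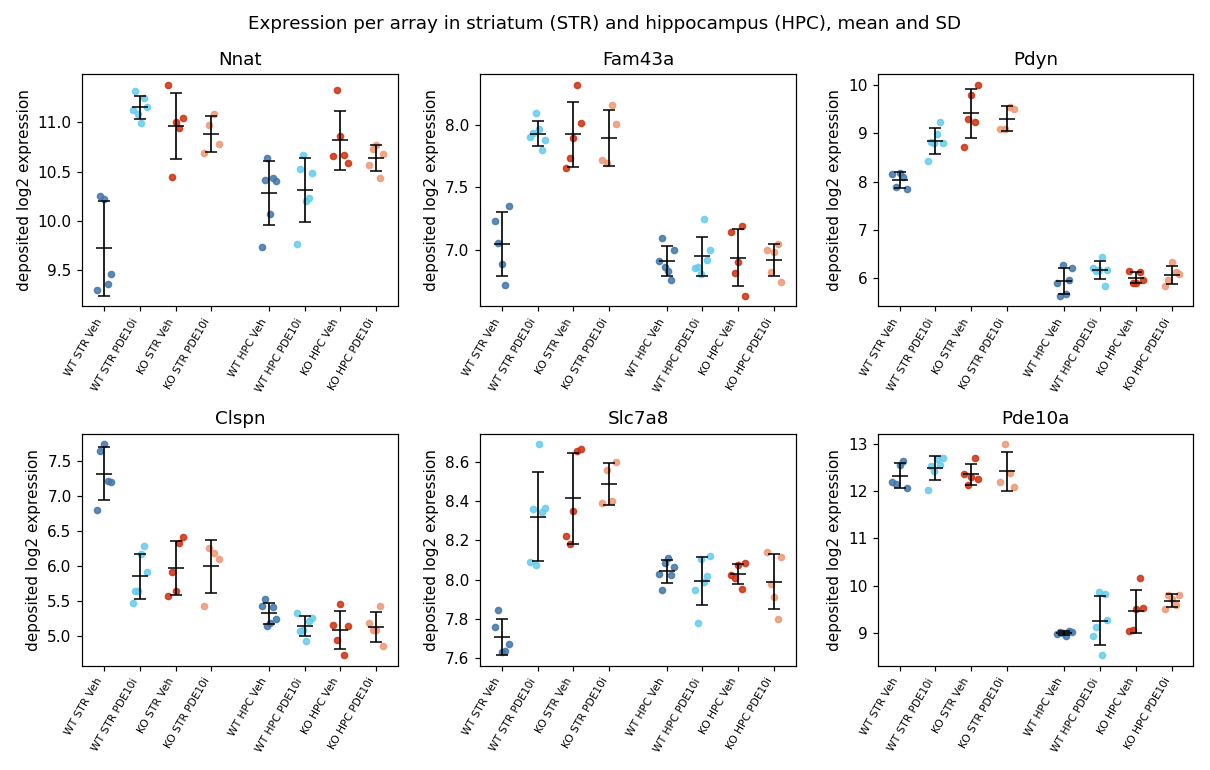
Log2 signal of Nnat, Fam43a, Pdyn, Clspn, Slc7a8 and Pde10a (vertical axes) on each array of the 8 groups; points are arrays, bars the mean and SD. In striatum Nnat rose 2.69-fold with the inhibitor in WT and 2.36-fold with the knockout label.

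The knockout label in striatum went with higher expression of Pdyn, 2.61-fold (log2 1.39 ± 0.19 SE, n = 5 against 5, adjusted p = 0.00451), Nnat, 2.36-fold (1.24 ± 0.18), and Fam43a, 1.83-fold (0.88 ± 0.13). Dusp14, a dual-specificity phosphatase, rose 1.75-fold (0.81 ± 0.14), Coch 1.74-fold, the amino acid transporter gene Slc7a8 1.63-fold (0.71 ± 0.11), Chmp1b, of the ESCRT membrane-remodelling machinery, 1.49-fold and the ubiquitin ligase gene Trim17 by 0.58 ± 0.11 on the log2 scale (its other probe set by 0.07 ± 0.10). Clspn fell 2.55-fold (-1.35 ± 0.21, adjusted p = 0.00741, its other probe set -0.08 ± 0.10), the troponin gene Tnnt2 1.84-fold, the sialidase gene Neu2 1.83-fold, Ptprv 1.74-fold, Gask1b 1.72-fold and Zfp40, a zinc finger gene of chromosome 17, 1.69-fold (-0.76 ± 0.11). Otof, which codes for a calcium sensor of vesicle release, fell 1.52-fold and the potassium channel subunit gene Kcns2 1.46-fold.

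Of 19 neuropeptide genes 1 rose (Pdyn), 0 fell and 18 did not pass. Adjusted over the list alone 3 rose, the others being Cartpt (2.21 ± 0.65) and Scg2 (0.71 ± 0.18), and the set test pointed up (adjusted p = 0.00256; adjusted p = 0.404 with an estimated correlation). Early response genes, which follow neuronal activity and CREB, were positive for 25 of 30 (median 0.22, adjusted p = 7.29e-05; adjusted p = 0.404 with an estimated correlation). None passed over all genes, and adjusted over the list alone Crem (0.93 ± 0.22), Fosl2 (1.03 ± 0.29) and Per1 (0.55 ± 0.14) did. Heat shock and ER chaperones were positive for 16 of 17 (adjusted p = 0.00122) and astrocyte markers negative for 10 of 10 (adjusted p = 0.00122), with no member past the threshold in either, also adjusted over the list alone. Both had an adjusted p of 0.404 with an estimated correlation. Oxidative phosphorylation genes were positive for 57 of 78 (adjusted p = 0.0168; adjusted p = 0.955 with an estimated correlation) and cytosolic ribosomal protein genes negative for 31 of 41 (adjusted p = 0.0371; adjusted p = 0.898 with an estimated correlation), again with 0 past the threshold. Shared striatal projection neuron genes were positive for 14 of 25 (adjusted p = 0.984).

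In all, 25 genes passed (11 higher and 14 lower, 1 with a clone name), 2 of them on chromosome 17 (Zfp40 and H2-DMa), against 1081 with an unadjusted p under 0.05. With array weights the count was 87, with only the groups compared 9, without KO vehicle 25 and WT inhibitor 13, 14 and 15 it was 145, and without the array of highest Gapdh difference in each striatal group it was 0. That difference was 0.39 ± 0.37 (SD, n = 5) on WT vehicle and 0.26 ± 0.20 (n = 5) on KO vehicle arrays. Leaving out WT vehicle 4 gave 8 genes, KO vehicle 28 gave 10, KO vehicle 26 gave 12, KO vehicle 29 and WT vehicle 3 gave 13 each, KO vehicle 30 and WT vehicle 2 gave 15 each, WT vehicle 1 gave 16 and KO vehicle 25 gave 82.

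Of the 33 genes that passed for the drug and the 25 that passed for the knockout label in striatum, 10 passed in both. Nnat, Fam43a, Slc7a8 and Coch rose and Clspn, Fst, Gask1b, Otof, Ptprv and Rnf144a fell in both: Fam43a by 0.88 ± 0.12 and 0.88 ± 0.13, Slc7a8 by 0.61 ± 0.11 and 0.71 ± 0.11 on the log2 scale. With all arrays 0 genes passed in opposite directions. Independent lists of these lengths would share 0.0109 rising and 0.0115 falling genes, but the 2 effects share their vehicle arrays. Without KO vehicle 25 and WT inhibitor 13, 14 and 15, 19 genes passed in the same direction and 18 in opposite directions, among the latter Nr4a1 (-1.44 with the drug and 1.17 with the knockout label) and Rgs4 (1.08 and -1.20), both chosen after their values were seen. Across all 18193 genes, which are not independent replicates, the changes correlated with r = 0.393 (Spearman rho 0.479), against a mean of 0.522 in 100 simulated pairs of unchanged groups with common vehicle arrays. With separate vehicle arrays the median r was 0.0959 (-0.331 to 0.292) over 20 splits, with the same sign for 51.6% of genes. The covariance was 0.00822 observed and 0.00826 simulated. Without KO vehicle 25 r was 0.206, and without all 4 striatal arrays of doubtful score it was 0.0683. The 10 shared genes became 3 without WT inhibitor 11 and 16 without KO vehicle 25.

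**Figure D3:**
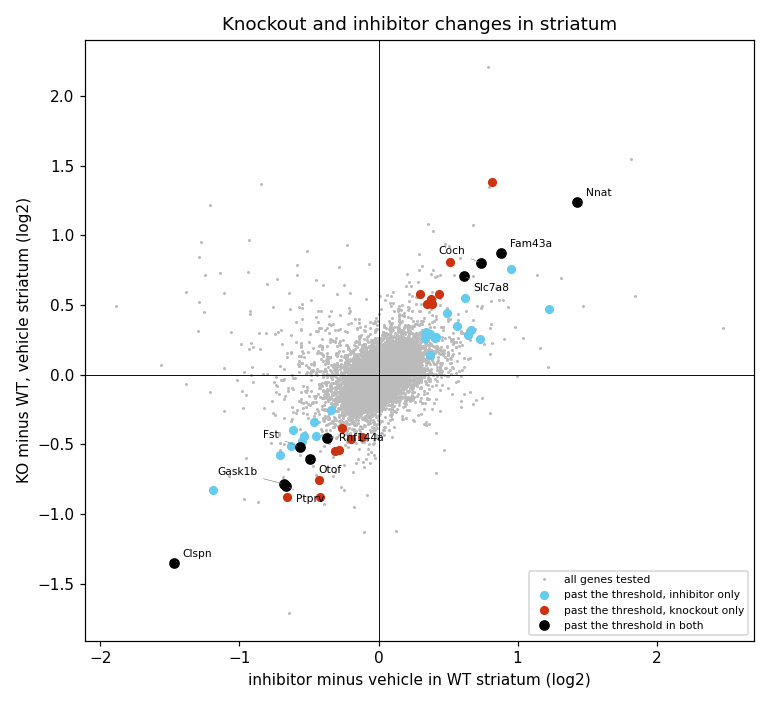
Log2 change with the inhibitor in WT striatum (horizontal axis) against log2 change with the knockout label (vertical axis) for each tested gene; coloured points passed the threshold in 1 or both effects. Nnat (1.43, 1.24) and Clspn (-1.47, -1.35) lie farthest out among the genes that passed in both.

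In striatum labelled KO the inhibitor moved no gene past the threshold. Nnat changed by -0.08 ± 0.19 (SE, n = 4 against 5), Fam43a by -0.03 ± 0.13, Clspn by 0.02 ± 0.22 and Pdyn by -0.11 ± 0.20. Of the 33 genes that passed in WT, 8 had the same sign in KO, and their median change in the WT direction was 0.61 in WT and -0.08 in KO. The limma fit gave 0 genes, with 257 at an unadjusted p under 0.05, and 0 without KO vehicle 25 and WT inhibitor 13, 14 and 15 (227). Camera with a preset correlation called 5 lists, all downward and all with an adjusted p of 0.831 with an estimated correlation: oxidative phosphorylation (10 of 78 positive, adjusted p = 2.05e-07), shared striatal projection neuron genes (2 of 25 positive, 4.76e-04), choroid plexus (0 of 11, 0.00283), thalamic (0 of 10, 0.0115) and vascular markers (1 of 10, 0.0409). No member of them passed, also adjusted over the list alone. The glutamatergic markers averaged 7.74 ± 0.21 (SD, n = 5) on KO vehicle and 7.80 ± 1.22 (n = 4) on KO inhibitor arrays.

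The difference between the drug's effect in WT and in KO striatum was tested directly. It was largest in evidence for Nnat (1.51 ± 0.26, adjusted p = 0.115) and Ankrd35 (-0.67 ± 0.12, adjusted p = 0.115), so 0 of 18193 genes passed, with 1346 at an unadjusted p under 0.05. Adjusted over the 33 inhibitor genes alone, 32 differed. Those genes were chosen for their size in WT, which favours such a difference. A feature common to the WT vehicle arrays would also give it, and the test cannot tell this from an effect of the drug. Clspn, for example, lay at 6.80 to 7.75 on those arrays. On every other striatal array, KO inhibitor included, it lay at 6.42 or less. Without the 4 doubted striatal arrays 158 genes passed over all genes, and without the 4 arrays of high Gapdh difference 10 did. With the gene mean of probe sets 4 passed, and with any probe set or array weights 1 each. Leaving out KO vehicle 26, WT vehicle 2 or WT vehicle 3 gave 1 gene each.

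In WT hippocampus the inhibitor changed no gene past the threshold. The smallest adjusted p was 0.139, shared by Gprc5d (0.33 ± 0.06, n = 6 against 6), and 1948 genes had an unadjusted p under 0.05. Cholesterol synthesis genes were negative for 13 of 14 (adjusted p = 1.96e-04), with Sc5d (-0.21 ± 0.05), Mvd (-0.26 ± 0.08) and Idi1 (-0.19 ± 0.07) passing adjusted over the list alone. All 10 microglia markers were negative (adjusted p = 5.06e-04), with Cd68 (-0.33 ± 0.09) and P2ry12 (-0.32 ± 0.09) passing adjusted over the list alone. Oxidative phosphorylation genes were negative for 63 of 78 (adjusted p = 1.75e-05). All 5 hypothalamic markers were positive (adjusted p = 0.00929), with Avp (0.22 ± 0.07) and Hcrt (0.23 ± 0.09) passing adjusted over the list alone, and ribosomal protein genes were negative for 34 of 41 (adjusted p = 0.00989, 0 adjusted over the list alone). With an estimated correlation the adjusted p was 0.561 for the first 4 of these lists and 0.817 for the ribosomal list. Fry called no list by direction, while its test for change in either direction passed for oxidative phosphorylation (adjusted p = 0.0174). Hippocampal subfield markers were positive for 1 of 11 but were not called (camera adjusted p = 0.113). They averaged 8.51 ± 0.73 (SD, n = 6, lowest array 7.04) on WT inhibitor and 8.76 ± 0.14 (n = 6) on WT vehicle arrays. Array weights in the limma fit gave 154 genes, leaving out WT inhibitor 10 gave 14, and leaving out the 4 hippocampal arrays of doubtful score gave 0 (1003 at an unadjusted p under 0.05).

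In hippocampus no gene passed for the knockout effect in limma (1205 at an unadjusted p under 0.05). The smallest adjusted p, 0.371, included Lix1 (-0.39 ± 0.07, n = 5 against 6) and Tmem181a (0.59 ± 0.12), both on chromosome 17. Microglia markers were negative for 10 of 10 (adjusted p = 2.26e-04, P2ry12 at -0.39 ± 0.10 adjusted over the list alone) and cholesterol synthesis genes for 12 of 14 (adjusted p = 0.00831, Sc5d at -0.24 ± 0.06 adjusted over the list alone). Oligodendrocyte and myelin markers were negative for 9 of 11 (adjusted p = 0.00977) and ribosomal protein genes for 31 of 41 (adjusted p = 0.0338), while all 17 chaperone genes were positive (adjusted p = 0.00831). Each of these 5 lists had an adjusted p of 0.875 with an estimated correlation. The early response kinase Sik1 was at 0.31 ± 0.07 and passed adjusted over the list alone, with 8 of 30 early response genes positive. Without the 4 hippocampal arrays of doubtful score 15 genes passed for the knockout effect. Those arrays were left out for their chromosome 17 genes, which favours genes of that chromosome in this count.

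In KO hippocampus the inhibitor changed 0 genes in the limma fit (695 at an unadjusted p under 0.05), and 0 without the 4 hippocampal arrays of doubtful score (389). All 15 glucocorticoid-responsive genes were positive, with no member past the threshold (adjusted p = 2.58e-04; adjusted p = 0.764 with an estimated correlation). The genotype by treatment difference in hippocampus gave 0 genes in limma (2151 at an unadjusted p under 0.05), 0 without the 4 doubted arrays (692) and 1 without WT inhibitor 13.

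Striatum and hippocampus of WT vehicle mice differed in the genes that define their neurons. All 25 shared striatal projection neuron genes were higher in striatum, led in evidence by Rgs9 (21.1-fold) and the retinoic acid receptor Rarb (17.1-fold). Of 6 indirect pathway markers 5 were higher, among them Gpr6 (63.0-fold; log2 5.98 ± 0.28 SE, n = 5 against 6), the dopamine receptor Drd2 (42.4-fold) and the enkephalin precursor Penk (23.8-fold). Of 10 direct pathway markers 9 were higher, with Slc35d3 (29.2-fold), Drd1 (23.8-fold) and the substance P precursor Tac1 (23.4-fold), and 1 was lower. Syndig1l (31.5-fold), Ido1 (26.4-fold), Scn4b (24.9-fold) and Dmkn (23.9-fold) were the other largest differences. Among 18 phosphodiesterases 9 were higher and 5 lower, with Pde7b (10.6-fold) and Pde1b (7.68-fold) next to Pde10a itself (9.99-fold). Hippocampus had more of the lactase gene Lct (33.8-fold), the desmosomal Dsp (19.3-fold), Neurod6 (16.1-fold), Spink8 (15.3-fold), Prdm8 (15.3-fold), C1ql2 (14.2-fold), Shisa6 (13.7-fold) and Cabp7 (13.6-fold).

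Of 11 hippocampal subfield markers 9 were lower in striatum, among them Fibcd1 (6.66-fold) and Cpne7 (6.07-fold), and 0 were higher. Cholinergic and basal forebrain markers were higher for 5 of 7 (Lhx8 9.73-fold, Ecel1 5.29-fold). These lists and the phosphodiesterases were called by camera with both correlations, at adjusted p = 3.56e-05 for the shared striatal and indirect pathway lists, 2.90e-04 for the direct pathway, 0.0205 for hippocampal subfields, 0.0249 for cholinergic markers and 0.0487 for phosphodiesterases with an estimated correlation. With the preset correlation 4 further lists were called: glutamatergic markers (7 of 9 lower, Neurod1 10.5-fold; adjusted p = 1.98e-06), oligodendrocyte and myelin markers (10 of 11 higher, Ugt8a 1.63-fold; 3.95e-04), circadian clock genes (6 higher and 2 lower of 16, Npas2 3.09-fold; 0.0369) and transmitter genes (8 higher and 4 lower of 19, Slc32a1 3.15-fold; 0.0217). Their adjusted p with an estimated correlation was 0.160, 0.451, 0.411 and 0.160. In all 6160 genes differed (2901 higher and 3259 lower in striatum), and between 4837 and 6754 did when 1 array was left out.

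The drug's effect differed between the regions for 39 genes in WT, 28 with a higher and 11 with a lower change in striatum. For Nnat the change was 1.43 in striatum and 0.03 in hippocampus (difference 1.40 ± 0.24 SE, adjusted p = 0.00513), and for Pde1c 0.95 and -0.24 (1.20 ± 0.23). Irak3 (1.24 ± 0.27), Myo3b (1.22 ± 0.26), Sox17 (0.88 ± 0.17), Fam43a (0.84 ± 0.15), the chloride channel gene Cftr (0.77 ± 0.17), Ppp1r2 (0.70 ± 0.13) and Abat (0.42 ± 0.09) had higher changes in striatum. Clspn (-1.30 ± 0.23), Ptprv (-0.91 ± 0.15), Fst (-0.90 ± 0.15), Otof (-0.81 ± 0.18), Fblim1 (-0.57 ± 0.10), the histone deacetylase Hdac4 (-0.55 ± 0.12), Ago4 (-0.48 ± 0.11) and Tm4sf4 (-0.46 ± 0.10) had lower ones. Of the 33 striatal inhibitor genes 10 had the same sign in hippocampus and 20 differed between the regions. A feature common to the striatal WT vehicle arrays would give such differences as well. The count of 39 became 23 with the gene mean of probe sets, 617 with array weights, 785 without the 8 doubted arrays and 280 without the 4 arrays of high Gapdh difference. Single arrays gave 19 (without striatal WT inhibitor 12), 22 (striatal 11), 23 (striatal 10), 24 (hippocampal WT vehicle 3), 25 (hippocampal WT inhibitor 12), 91 (hippocampal 10), 122 (striatal 13) and 154 (striatal 14).

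The knockout effect differed between the regions for 9 genes. Pdyn (1.39 in striatum and 0.06 in hippocampus; difference 1.32 ± 0.22 SE, adjusted p = 0.0135), Dusp14 (1.04 ± 0.22), Fam43a (0.85 ± 0.16), Slc7a8 (0.72 ± 0.13) and Chmp1b (0.58 ± 0.12) had higher changes in striatum, and Gask1b (-0.94 ± 0.18), Ptprv (-0.89 ± 0.16), Fst (-0.83 ± 0.16) and Cgref1 (-0.61 ± 0.12) lower ones. Of the 25 striatal knockout genes 17 had the same sign in hippocampus. The count was 2 with only the groups compared, 5 without the 4 arrays of high Gapdh difference, 23 with array weights and 34 without the 8 doubted arrays. With a block on the number in the title no gene passed, though the numbers are not shown to pair the arrays. Leaving out hippocampal KO vehicle 26, striatal KO vehicle 28 or striatal WT vehicle 4 gave 2 genes, hippocampal WT vehicle 2 gave 3, striatal KO vehicle 29 gave 4, hippocampal KO vehicle 25 or 30, hippocampal WT vehicle 4 or striatal WT vehicle 3 gave 5, and striatal KO vehicle 25 gave 28.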

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

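All tests of the 3 patterns below were chosen after the results had been seen, as were the fits without the doubted arrays or with the Gapdh difference as a term, while the counts over other splits were set earlier.

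Chromosome 17 genes stood out among the striatal knockout differences, 16 of 96 with a p under 0.001. Their median distance from Pde10a was 90 genes against 390 for all genes of the chromosome (permutation p = 1.9e-04, one-sided, 100000 permutations), as a segment of another strain carried along with the targeted allele would give. Examples are Prr18, 2 genes away (-0.61 in striatum and -0.46 in hippocampus), and Fndc1, 10 genes away (0.84 and 0.82). If the loss of the enzyme acted in proportion to its level, the hippocampal median would be 0.0475 at most, and it was 0.24 with a bootstrap SD of 0.0998, while 15 of the 16 kept their sign there against 44 of 80 knockout genes of other chromosomes (Fisher's exact test, two-sided, p = 0.00386). A strain segment may thus account for these genes. The hippocampal median lay within 2 bootstrap SDs of the bound, so an effect in proportion to the enzyme was not excluded. That median was computed with all arrays, among them KO vehicle 25 and 26, whose chromosome 17 scores (-0.02 and 0.09) lay at the WT level. They may have made it smaller, which was not tested. An effect of the enzyme, whether or not it follows its level, cannot be told apart from a strain segment with 1 knockout line.

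Arrays whose chromosome 17 score lies on the other genotype's side numbered 4 in each region. In striatum, 100 genes outside chromosome 17 placed KO vehicle 25 at 0.878 on an axis from KO vehicle (0) to WT inhibitor (1), each array held out of its own reference, inside the 0.871 to 1.02 of the undoubted WT inhibitor arrays, so it may be a WT inhibitor array under a wrong label. WT inhibitor 13 and 15 lay at 0.425 and 0.563, above the other KO vehicle arrays (at most 0.0686). Their scores of 0.631 and 0.607 lay below those of the other KO arrays (at least 0.892). Both argue against whole KO vehicle arrays under their labels. For WT inhibitor 14 (0.216, score 0.784) this cannot be told apart. It too lay above the other KO vehicle arrays, but its score was not under the limit of 0.742 used for this test. KO inhibitor 35 lay at 0.216 as well. RNA of both genotypes mixed on these 3 arrays cannot be told apart from other causes either, since WT vehicle arrays lay at 0.199 to 0.586 on the same axis. In hippocampus 2 WT inhibitor arrays (12 and 14) had the KO level and 2 KO vehicle arrays (25 and 26) the WT level, each within 0.170 of it, so whole arrays exchanged between these 2 groups may account for them, and animals whose segment parted from the label cannot be told apart from this, because 4 of 20 pairs with the same number in both regions differ in score side and the numbers are not shown to mark animals.

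With all arrays, the striatal genes that passed for the inhibitor or the knockout label had the same sign in the other effect. Across all genes the shared vehicle arrays may account for this, since the observed covariance differed from the simulated one by -3.81e-05 (simulated SD 4.10e-04, genes drawn independently), but genes chosen in either effect with some vehicle arrays kept their sign in the other effect, computed with the remaining vehicle arrays, for a median of 87.9% (33 inhibitor genes, 63.6 to 97.0) and 92% (25 knockout genes, 76 to 100) over 20 splits. Such splits leave a difference common to all WT vehicle arrays in both effects, so they cannot exclude it. For example, Nnat lay at 9.30 to 10.26 on those arrays and at 10.44 or more on every other striatal array, KO inhibitor included. Their array medians averaged 6.11, against 6.09 in the other striatal groups. Without the doubted arrays the median shares of the same sign over the splits were 31.8% and 40%. The genes were chosen anew without those arrays and may be other genes. These shares thus cannot say whether arrays out of place account for the like direction of the genes chosen with all arrays. In the fit without the doubted arrays 19 genes passed in the same direction and 18 in opposite ones, and 418 of 769 inhibitor genes had the same sign. No value for unchanged groups with shared vehicle arrays was computed for these counts. For the 10 genes that passed in both, 9 still did without the doubted arrays and 9 with the Gapdh difference as a term, which argues against either as their whole cause, but shared vehicle arrays were not excluded for them, and a shared effect of blocking and of losing PDE10A stays open and untested. Without the 4 arrays of high Gapdh difference 0 passed in both. Fewer arrays entered that fit. As many striatal arrays were left out with the doubted arrays, where 9 still passed, but the sets are not alike. The high-Gapdh set took out an array of every striatal group, among them WT vehicle 4, which both effects share. It kept WT inhibitor 14 and 15 and KO vehicle 25, which are doubted, while the doubted set kept every WT vehicle array. The fits thus cannot tell fewer arrays from RNA quality, and some dependence on RNA quality is not excluded. The knockout difference of Nnat stayed similar in size (1.24 ± 0.18 to 1.16 ± 0.21, limma adjusted p = 0.0995).

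Single arrays lay far from their group in 3 of 80 groups tested by the gap to the nearest other array over the group's range. Chance flags about 1 in 20 groups. The Gapdh difference of WT striatal vehicle 4 was 1.05 with the nearest at 0.283 (ratio 0.881). The chromosome 17 score of KO striatal vehicle 25 was 0.194 with the nearest at 0.892 (ratio 0.870). That of WT hippocampal vehicle 4 was -0.129 with the nearest at 0.00571 (ratio 0.721).

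The inhibitor effect in WT differed between striatum and hippocampus for 39 genes and the knockout effect for 9, by a test of the difference itself. Among 100 splits of the arrays, drawn at random and including the real one, chance can be excluded for the first (39 genes, highest other 2, 1 split as large). For the second 3 splits were as large and a random one gave more genes than the real one (9 genes, highest other 14). This number of splits met the rule set beforehand for excluding chance. Since a random split gave more genes, chance is still left open for the knockout effect between regions.

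Chance can also be excluded for the inhibitor effect in WT striatum (33 genes, highest other 1, 1 split as large), the striatal knockout effect (25, highest other 12, 1 split) and striatum against hippocampus (6160, highest other 4293, 1 split). Where 0 genes passed in limma, all 100 splits are as large whatever the data, so this count says nothing about chance. These were the inhibitor effect in KO striatum (highest other 0; 257 genes at an unadjusted p under 0.05), the striatal genotype by treatment difference (22; 1346), and in hippocampus the inhibitor effect in WT (1; 1948), the knockout effect (1; 1205), the inhibitor effect in KO (3; 695) and the genotype by treatment difference (17; 2151). In the comparisons with 22 and 17, 2 other splits each gave any gene, which may reflect a structure of the samples and was not tested.

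Among 10092 probe sets without a single named gene, which the comparisons above do not use, some passed the threshold. There was 1 for the inhibitor effect in WT striatum (higher), 11 for the striatal knockout effect (8 higher and 3 lower) and 1 for the striatal genotype by treatment difference. Striatum against hippocampus gave 2421 (1627 higher and 794 lower), the region by inhibitor difference 1 and the region by knockout difference 5 (3 higher and 2 lower).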

How the results depend on the processing

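Fits without the 8 doubted arrays or the 4 arrays of high Gapdh difference, and those with the Gapdh difference or the glutamatergic marker mean as a covariate, were chosen after seeing the data; the others were planned. The cause of a change was not tested, and fewer arrays or genes in a fit may be part of it. Over genes and settings, 2901 values past the threshold stayed past it in the same direction, 480 no longer passed and 3 reversed; of values not past it 7069 stayed, 107 passed and 11 moved. Of list results, 16 stayed and 62 no longer passed.

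The inhibitor effect in WT striatum (33 genes) gave 19 with the gene mean of probe sets, 18 with any probe set, 195 with array weights, 20 with only the groups compared, 769 without the doubted arrays (32 of the 33 kept), 86 without the high-Gapdh arrays (23 kept) and 10 with the marker covariate. The knockout effect (25) gave 87 with array weights, 9 with only the groups compared, 145 without the doubted arrays (24 kept) and 0 without the high-Gapdh arrays. The striatal genotype by treatment difference (0) gave 4 with the gene mean of probe sets, 1 with any probe set, 1 with array weights, 158 without the doubted arrays and 10 without the high-Gapdh arrays. In hippocampus the inhibitor effect in WT (0) gave 154 with array weights, and the knockout effect (0) gave 15 without the doubted arrays. The region by inhibitor difference (39) gave 23 with the gene mean of probe sets, 617 with array weights, 785 without the doubted and 280 without the high-Gapdh arrays. The region by knockout difference (9) gave 23 with array weights, 2 with only the groups compared, 34 without the doubted and 5 without the high-Gapdh arrays.

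The correlation of knockout and inhibitor changes (0.393) was 0.0959 with split controls and 0.0683 without the doubted arrays. Genes passing in both in the same direction (10, with 0 in opposite directions) were 19 without the doubted arrays (18 in opposite directions) and 0 without the high-Gapdh arrays.

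Single probe sets turned the sign of a Pde10a difference, none of them past the threshold: striatal knockout effect -0.33, inhibitor effect in KO striatum -0.13, -0.0368, -0.0623 and -0.0219, hippocampal knockout effect -0.0188, hippocampal genotype by treatment difference -0.36 and -0.37, region by inhibitor difference 0.23 and 0.15, region by knockout difference 0.10 and 0.19. For striatum against hippocampus, the gene mean of probe sets reversed Rpl22 (-0.0151), Rps20 (-0.0520) and Cx3cr1 (-0.0797), which were then no longer past the threshold. For Clspn under the inhibitor 1 of 2 probe sets had the opposite sign.

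List calls by direction went to 0 with an estimated correlation and 0 with fry in 6 comparisons: inhibitor effect in WT, knockout effect and inhibitor effect in KO, each in striatum and in hippocampus. For striatum against hippocampus they were 6 and 16. Fry's test for change in either direction passed for 1 list of the inhibitor effect in WT in each region.

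Leaving out each array in turn gave 4 to 73 genes for the inhibitor effect in WT striatum, 8 to 82 for the knockout effect, 0 to 0 for the inhibitor effect in KO and 0 to 1 for the genotype by treatment difference. In hippocampus the ranges were 0 to 14, 0 to 0, 0 to 0 and 0 to 1 in the same order. They were 4837 to 6754 for striatum against hippocampus, 19 to 154 for the region by inhibitor and 2 to 28 for the region by knockout difference, 0.206 to 0.489 for the correlation and 3 to 16 for genes passing in both. Pde10a differences ran from 0.10 to 0.26, -0.0597 (without KO vehicle 29) to 0.11, -0.13 (without KO inhibitor 35) to 0.17 and -0.00592 (without KO inhibitor 39) to 0.30 in striatum, 0.14 to 0.41, 0.29 to 0.57, 0.11 to 0.40 and -0.13 (without KO vehicle 29) to 0.19 in hippocampus, 3.24 to 3.39 between regions, -0.24 to 0.0257 (without hippocampal WT inhibitor 12) for the region by inhibitor and -0.54 to -0.26 for the region by knockout difference.

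With a replicate block on the number shared by arrays of both regions, striatum against hippocampus gave 5554 genes, the region by inhibitor difference 26 and the region by knockout difference 0. The numbers are not shown to pair the arrays: over 20 pairs the correlation of residuals ran from -0.38 to 0.31, 6 were over 0.1 and 4 were highest with their own number.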

Other observations

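The fits without the 8 doubted arrays, and the genes singled out here, were chosen after the values were seen.

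With the doubted arrays left out (WT inhibitor n = 3, WT vehicle n = 5), the inhibitor's profile in WT striatum widened to 769 genes in limma. The remaining WT inhibitor arrays had glutamatergic marker means of 5.94 to 6.61, against an average of 7.48 on WT vehicle arrays. These markers had a median change of -1.47 (camera adjusted p = 3.35e-04, or 0.7725 with an estimated correlation). How far this difference bears on the changes below was not tested. Nts rose 10.6-fold (log2 3.41 ± 0.25 SE, adjusted p = 8.61e-07), Rgs5, a pericyte marker, 1.96-fold (0.97 ± 0.09) and the activin subunit gene Inhba 2.10-fold (1.07 ± 0.11). Ciart, a clock repressor, rose 2.60-fold (1.38 ± 0.12) and the clock activator Arntl fell 1.68-fold (-0.75 ± 0.11). Nr4a1 (2.72-fold; -1.44 ± 0.20), an early response gene, and the neuropeptide precursor gene Vgf (2.63-fold; -1.39 ± 0.15) fell. Of the 30 early response genes 3 rose and 3 fell (11 adjusted over the list alone; camera adjusted p = 0.0918; adjusted p = 0.779 with an estimated correlation). Vascular markers rose for 7 of 10 (8 adjusted over the list alone; adjusted p = 0.00409 with an estimated correlation and 2.67e-06 with fry). Oxidative phosphorylation genes rose for 11 of 78 (38 adjusted over the list alone; adjusted p = 0.0468 with an estimated correlation and 6.20e-05 with fry).

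In the same fit the knockout label (n = 4 against 5) gave 145 genes, with Cartpt, a neuropeptide precursor, up 6.73-fold (2.75 ± 0.32) and the transcription factor genes Fosl2 2.42-fold, Nr4a1 2.25-fold and Crem 2.19-fold. Early response genes rose for 5 of 30 (11 adjusted over the list alone; camera adjusted p = 3.72e-12; adjusted p = 0.202 with an estimated correlation). Of the genes that passed in both effects, 19 moved in the same direction and 18 in opposite directions. Independent lists of these lengths would share 2.93 genes in the same and 3.19 in opposite directions. The 2 effects share their vehicle arrays, and no value for unchanged groups with shared arrays was computed for these counts. Among the opposite ones were Nr4a1 (-1.44 with the inhibitor and 1.17 with the knockout label), Vgf (-1.39 and 0.79), Egr1 (-0.66 and 0.60), Etv5 (-1.03 and 0.75) and the signalling regulator Rgs4 (1.08 and -1.20). Of the 769 genes 418 had the same sign in the knockout effect, and 342 had the same sign for the inhibitor in KO striatum. The difference between the drug's effect in WT and in KO was past the threshold for 158 genes.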
